A study of Mus musculus with 24 samples.

How the data were processed

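RNA of J774.16 macrophages was measured on 24 Affymetrix mouse arrays, 4 in each of 6 groups: control cells, cells with live *Cryptococcus neoformans* and cells with heat-killed yeast, at 2 h and 24 h. The values used are the table of probe sets by 24 arrays that the authors deposited, on a log2 scale as judged from their range, and no column was left out. Per the submitters' processing notes, the tools were RMA, oligo and limma, whose versions are not given in the sources used here. The log base, the background step and the genome build are likewise not given in the sources used here. The sorted values of the deposited columns lie within 0.26 log2 of their mean. They were therefore taken as normalised between arrays before deposition, which was not tested, and no further normalization was applied in the fits reported. The labels give no signal over background and no number of cells per array, so the depth behind each value is unknown, and the number of arrays limits the precision.

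Probe sets were named from the probe annotation of the array. It lists exactly 1 gene symbol for 21789 probe sets, several for 1621 and no gene for 5534. Of the 21789, 21698 matched the mouse gene table by their Entrez identifier. Each gene was represented by its probe set with the highest mean over all arrays (999 genes had more than 1), which gave 19938 genes. No filter on level was applied.

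The fits used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). All 24 arrays were fitted in 1 linear model of the 6 group means (18 residual degrees of freedom), followed by empirical Bayes moderation, a 2-sided limma test of each contrast and Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. The 10 contrasts were live against control, heat-killed against control and live against heat-killed at each time, control at 24 h against control at 2 h, and 3 interactions of yeast with time. Log2 differences are first group minus second, SE is the moderated standard error of a difference, and levels of a group are means ± SD of 4 arrays.

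The 39 gene lists, at least 5 measured members each, were written before the data were examined. So were the groups, the contrasts, the tests of genes and lists, the rule for naming genes and all alternative settings except the 4 named as added. Tests of explanations that were chosen after a result was seen are marked as such where they are given. The lists cover NF-kB cytokines and chemokines, immediate early genes, interferon-stimulated genes, the nuclear respiratory chain, the tricarboxylic acid cycle, the mitochondrial ribosome, mitochondrial dynamics and mitophagy, cytosolic ribosomal proteins, translation factors and ribosome biogenesis. They further cover the unfolded protein response with its endoplasmic reticulum chaperones, the integrated stress response, heat shock, hypoxia and HIF-1 targets, glycolysis, p53 and DNA damage, DNA replication and G1/S, mitosis and G2/M, cyclins D and CDK inhibitors, apoptosis regulators, NRF2 targets, and metallothionein with metal handling. The others are lysosome and phagosome, autophagy, phagocytic and pattern recognition receptors, inflammasome and pyroptosis, antigen presentation, alternative activation and repair, cholesterol biosynthesis, lipid efflux and fatty acid metabolism, actin and podosomes, histone genes, proteasome, macrophage identity, and markers of T cells, B cells, neutrophils, fibroblasts and epithelium.

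Each list was tested against all other genes with limma's camera at the preset correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the 39 lists of a comparison. A call means a camera adjusted p under 0.05 at that preset. Beside it stand camera with the correlation estimated from the data, and fry, which tests whether the genes of a list move, on balance, 1 way and compares them with no other genes. The mean of a list is the mean log2 difference of its members. The genes named were, for each comparison, the called genes whose 4 and 4 arrays do not overlap, up to a fixed number from either end, and for each list described up to 4 members with the smallest adjusted p. Where fewer than 5 genes passed, the 5 with the smallest unadjusted p were given as values that did not pass. Predicted genes, microRNAs and olfactory receptors were counted and not named. Genes outside the rule are said to be chosen after their values were seen.

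The array titles carry numbers in 4 runs of 6 arrays, 1 of each group, and whether these runs pair the arrays was checked by correlating deviations from the group means between arrays of the same number. The correlations within a run were 0.41 to 0.56 for live and control at 2 h, 0.39 to 0.55 for live and control at 24 h, 0.32 to 0.53 for heat-killed and control at 2 h and 0.49 to 0.66 for live and heat-killed at 2 h, with all 4 pairs above 0.1 and best matched with their own run. For heat-killed and control at 24 h they were 0.05 to 0.49 and for live and heat-killed at 24 h 0.005 to 0.55 (3 of 4 pairs above 0.1 in each), and for control cells at 24 h and 2 h −0.12 to 0.45 (2 of 4). The labels do not say what the runs are, so the fits reported ignore them, and fits with a run block were tried beside them.

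The other settings chosen before were the run as a fixed block and as a random block, the arrays of a contrast alone, intensity-trended robust moderation, array weights, leaving out the dimmer genes (those below the median mean level), the mean of a gene's probe sets, all probe sets, median scaling, quantile normalization, cyclic loess, each array left out in turn, camera with an estimated correlation, fry, values within each run, and controls split for the overlap of the 2 yeast arms. Added after the data were seen were run offsets fitted separately at each time, each run left out, an exact 2-sided permutation test of list means, and an overlap with the arms taken from different runs. The permutation test is judged by its unadjusted p, a choice made after its adjusted p was seen to be unable to pass (the smallest possible p is 0.0286). It exchanges the 8 arrays of a comparison freely and so ignores their pairing within runs. Splits of the 8 arrays of a comparison into 4 and 4 number 35, and interactions were relabelled 100 times.

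The method was tested on simulated data made from the 24 arrays, with changes of known size added to 50 genes per size in the live 24 h arrays. With the residuals of the arrays shuffled, 30.6% of genes changed by 0.5 log2 were called, 90.4% at 1 log2, 98.2% at 1.5 and 99.4% at 2, as means of 10 draws over 19938 genes. The number of draws was raised to 10 after the first was seen. A shift of 0.5 log2 in the glycolysis list was called in 10 of 10 draws at the preset correlation and in 5 of 10 with an estimated correlation. Of the 38 lists left unshifted, the preset correlation called a median of 5 (0 to 15) and the estimated correlation 0. With independent noise in place of array residuals both called 0. For this reason each list is given with both. The shuffle ran over all 24 arrays, so its groups did not hold 1 array of each run as the real groups do. Run offsets that cancel in the real comparisons were left in, so the rates of the shuffled data may not hold for the real comparisons.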

Results

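Transcript levels were measured on 24 Affymetrix expression arrays in J774.16 cells, a macrophage line derived from the mouse J774 line. Control cells were compared with cells given *Cryptococcus neoformans*, an encapsulated yeast that macrophages ingest and that can survive inside them. The 6 groups of 4 arrays were control cells, cells with live yeast and cells with yeast killed by heating at 60 °C for 60 min, each at 2 h and at 24 h. The yeast was added together with a monoclonal antibody to its capsule at 5 µg/mL, which coats the yeast for uptake, so the live and heat-killed arms shared the antibody and the labels name none for the control cells. The deposited table held log2 values with array medians between 5.44 and 5.63. Levels of 19938 genes were compared, each by 1 probe set. The p-values measure only the spread between these arrays, since the labels do not say whether the 4 arrays of a group come from separate cultures, and the number of arrays limits the precision.

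The arrays differed more by the run of numbers in their titles than by yeast. The titles fall into 4 runs of 6 arrays, each with 1 array of every group, and the run takes the replicate number (1 to 4). Over all genes the run took 30.9% of the variance (3 degrees of freedom) and its interaction with time 16.4% (3), against 11.9% for time (1) and 11.5% for yeast within a time (4). The rest took 29.3% (12 degrees of freedom). Part of each share is therefore spread between arrays, and 11.5% is not variance due to yeast alone. The first principal component held 26.2% of the variance and the second 10.7%. Correlations between arrays lay between 0.977 and 0.996 over 276 pairs, and no 2 arrays were copies of each other (lowest median absolute difference 0.12 log2).

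**Figure D1:**
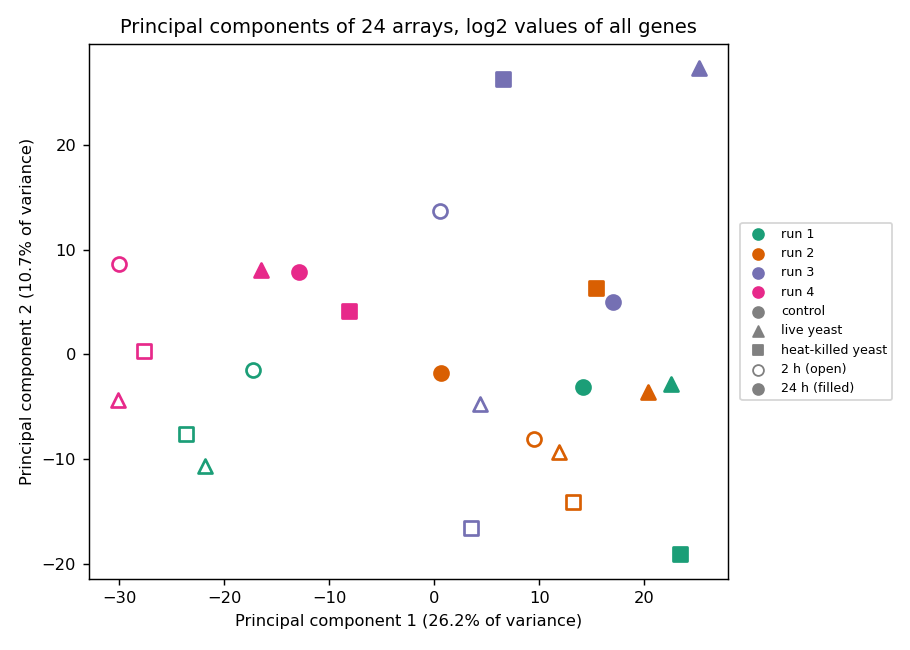
Scores of the 24 arrays on the first (26.2% of variance) and second (10.7%) principal components of all genes; colour gives the run (1 to 4), circles control, triangles live yeast, squares heat-killed yeast, open symbols 2 h and filled symbols 24 h. Along the first component, the run 4 arrays at 24 h lie between −16.5 and −8.16 and the other 24 h arrays between 0.68 and 25.2.

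Live yeast was compared with control cells at 24 h to find what live yeast, added with antibody, changes. Transcripts of the hypoxia list, targets of the oxygen-regulated transcription factor HIF-1, were higher with live yeast in 25 of 29 measured members. Their mean log2 level was 8.44 ± 0.23 (SD, n = 4) against 7.89 ± 0.19 in control cells, a mean of 1.46-fold. Fam162a, a mitochondrial protein induced by low oxygen, was 1.82-fold higher (log2 difference 0.87 ± 0.22 SE, n = 4 per group). Bhlhe40, a transcriptional repressor, was 1.95-fold higher (0.96 ± 0.25), and Egln1, the prolyl hydroxylase that marks HIF-1α for degradation, 1.65-fold (0.72 ± 0.21). Hif1a itself, chosen after its values were seen, was not higher (log2 −0.13 ± 0.15). Of the glycolysis list, the enzymes and transporters from glucose to lactate, 16 of 17 members were higher, with a mean of 1.33-fold (10.43 ± 0.19 against 10.02 ± 0.16, SD, n = 4). The glucose transporter Slc2a1 was 1.74-fold higher (0.80 ± 0.27), the neuronal-type enolase Eno2 1.95-fold (0.96 ± 0.36), and hexokinase Hk2 1.48-fold (0.57 ± 0.19; 0.36 without run 2).

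With limma, 0 of 19938 genes passed in this comparison at 24 h, where 760 had an unadjusted p under 0.05 and 997 would by chance (smallest adjusted p = 0.5). Without live 24 h replicate 4, 1 gene passed. That fit ignores the pairing of arrays within runs. Genes at an unadjusted p under 0.05 numbered 1333 with the fixed run block and 1791 with the run block within each time. The gene-set test camera, at its preset correlation, called both lists (hypoxia adjusted p = 3.42e-14, glycolysis adjusted p = 1.31e-08). Neither call held with an estimated correlation: hypoxia lay at the threshold (adjusted p = 0.05 with an estimated correlation, not below it) and glycolysis above it (adjusted p = 0.126 with an estimated correlation). Adjusted over the list alone, 15 hypoxia genes passed (Fam162a and Bhlhe40 at 0.0116, Egln1 and P4ha1 at 0.017) and 0 glycolysis genes. With the run block within each time 19 hypoxia and 9 glycolysis genes did. Both lists were higher in 4 of 4 runs: hypoxia by 0.27, 0.76, 0.87 and 0.29 log2 in runs 1 to 4, glycolysis by 0.24, 0.50, 0.75 and 0.14. Exact 2-sided permutation of the array means gave p = 0.0571 for hypoxia and p = 0.0286, the smallest that 4 against 4 arrays allow, for glycolysis (both p = 0.557 after adjustment over 39 lists). This permutation also ignores the pairing of arrays within runs, so its p carries spread between runs that cancels in the comparison. No single array or run left out changed either call at the preset correlation or moved either mean by more than 1.5-fold.

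**Figure D2:**
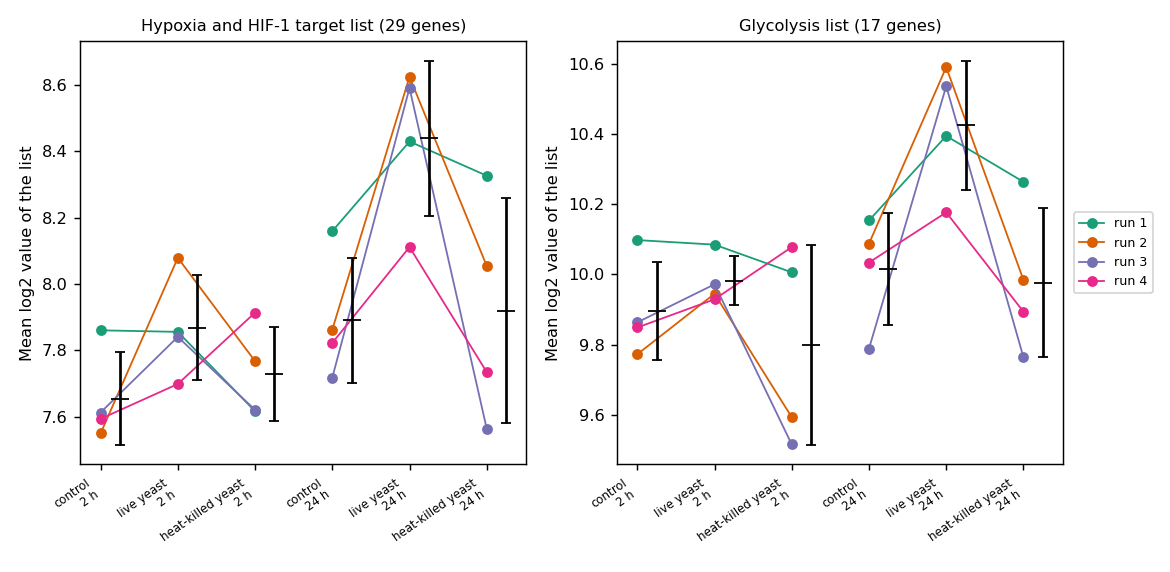
Mean log2 level of the 29 hypoxia and HIF-1 genes (left) and the 17 glycolysis genes (right) on each array, by group; coloured lines join arrays of a run within a time, and black bars give mean ± SD (n = 4). With live yeast at 24 h the hypoxia mean was 8.44 against 7.89 in control cells and 7.92 with heat-killed yeast.

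In the same comparison, the DNA replication, ribosome biogenesis, NRF2 and cholesterol biosynthesis lists were lower with live yeast at 24 h. All 49 members of the DNA replication and G1/S list were lower, with a mean log2 level of 8.06 ± 0.56 (SD, n = 4) against 8.45 ± 0.32 in control cells. Chaf1b, a chromatin assembly subunit, was 1.66-fold lower (log2 −0.74 ± 0.26 SE) and Pole2, a subunit of DNA polymerase epsilon, 1.64-fold lower (−0.71 ± 0.27; −0.43 without live 24 h replicate 3 and −1.09 without live 24 h replicate 4). Of the ribosome biogenesis list, 43 of 45 members were lower (9.31 ± 0.15 against 9.53 ± 0.17), among them Dkc1, the pseudouridine synthase dyskerin, 1.42-fold lower (−0.51 ± 0.18). The NRF2 antioxidant list was lower by a mean log2 of −0.18, with 21 of 28 members lower, and the cholesterol biosynthesis list by −0.21, with 18 of 19 lower. Camera called these lists at the preset correlation: DNA replication (mean log2 −0.38, adjusted p = 1.71e-18), ribosome biogenesis (−0.21, adjusted p = 2.12e-15), cholesterol (adjusted p = 4.86e-05) and NRF2 (adjusted p = 7.75e-05). None held with an estimated correlation (adjusted p = 0.41, 0.222, 0.423 and 0.301 with an estimated correlation). Adjusted over the list alone, 0 members of each passed without a run block, and 26 of DNA replication, 3 of ribosome biogenesis and 7 of NRF2 with the run block within each time. Ribosome biogenesis was lower in 4 of 4 runs (−0.11, −0.20, −0.39 and −0.16) and DNA replication in 3 of 4 (−0.48, −0.63, −0.49 and 0.07). The exact permutation p was 0.143 for ribosome biogenesis and 0.257 for DNA replication. The DNA replication mean was −0.24 without live 24 h replicate 3 and −0.65 without live 24 h replicate 4. The NRF2 mean was −0.12 without control 24 h replicate 2, and the cholesterol mean −0.12 without live 24 h replicate 1, −0.13 without control 24 h replicate 2 and −0.11 without run 1.

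The NF-kB, immediate early and alternative activation lists were higher with live yeast at 24 h, but their calls were lost without single arrays or runs. Of the NF-kB list of cytokines and chemokines, 34 of 39 were higher (mean log2 0.25), with Nos2, the inducible nitric oxide synthase, 2.37-fold higher (1.24 ± 0.40 SE, n = 4 per group). Of the immediate early genes, 32 of 33 were higher (0.23). Of the alternative activation list, 26 of 32 were higher (0.18), with arginase Arg1 1.57-fold (0.65 ± 0.27; 0.37 without run 2; log2 level 5.05 in control cells, below the array medians) and macrophage elastase Mmp12 2.33-fold (1.22 ± 0.74; 0.40 without control 24 h replicate 3). The heat shock list was lower by −0.08, with the chaperone partner Chordc1 1.41-fold lower (−0.50 ± 0.12), the 1 member that passed adjusted over the list alone. Camera at the preset correlation gave adjusted p = 0.00172 for NF-kB, immediate early and heat shock genes and 0.029 for alternative activation, and adjusted p = 0.423, 0.423, 0.126 and 0.301 with an estimated correlation, in the same order. The NF-kB mean was 0.03 without live 24 h replicate 3 and 0.15 without control 24 h replicate 4, where it was no longer called, and 0.39 without control 24 h replicate 3 or live 24 h replicate 4. The immediate early mean was 0.11 and not called without live 24 h replicate 3. The heat shock mean was −0.06 and not called without run 3. Alternative activation was not called without live 24 h replicate 1 (0.16) or 2 (0.13), control 24 h replicate 2 (0.19), 3 (0.14) or 4 (0.17), or run 2 (0.14).

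The remaining called lists of live yeast against control at 24 h were 6, all lower. They were mitosis (mean log2 −0.15, 44 of 49 members lower), proteasome (−0.09, 28 of 34), endoplasmic reticulum chaperones of the unfolded protein response (−0.08, 24 of 32), the mitochondrial ribosome (−0.06, 43 of 59), translation factors (−0.05, 23 of 36) and the tricarboxylic acid cycle (−0.07, 15 of 20). Camera's adjusted p lay between 4.86e-05 (mitosis) and 0.0246 (tricarboxylic acid cycle), and none held with an estimated correlation (adjusted p from 0.41 to 0.673 with an estimated correlation). Each of the 6 lost its call when some single array was left out. The mitosis mean went to 0.02 without live 24 h replicate 3, the chaperone mean to 0.03 without control 24 h replicate 3 and 0.01 without live 24 h replicate 4, the proteasome mean to −0.03 and the mitochondrial ribosome mean to −0.02 without live 24 h replicate 2, the translation factor mean to −0.03 without control 24 h replicate 3, and the tricarboxylic acid cycle mean to −0.04 without control 24 h replicate 4.

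With all 24 arrays, single genes passed between live yeast and control cells at 24 h when the pairing of arrays within a run was used. Fitting run offsets separately at each time, a choice made after the data were seen, called 23 of 19938 genes, 20 higher and 3 lower. Plod2, a lysyl hydroxylase of collagen, was 2.65-fold higher (log2 level 8.53 ± 0.34 against 7.13 ± 0.61, SD, n = 4; difference 1.40 ± 0.21 SE with the run block; adjusted p = 0.0167), Tgfb3, a transforming growth factor, 2.72-fold (1.44 ± 0.24; adjusted p = 0.0217), and the syndecan Sdc3 2.7-fold (1.43 ± 0.26; adjusted p = 0.0321). Echdc3 was 2.16-fold higher and the actin-binding Tmsb10 1.97-fold (adjusted p = 0.0167 for both). Slc7a11, a subunit of the cystine and glutamate exchanger, was 1.95-fold lower (−0.96 ± 0.17; adjusted p = 0.0321) and Pgd, an enzyme of the pentose phosphate pathway, 1.55-fold lower (−0.63 ± 0.12; adjusted p = 0.0487). Tbcd was the remaining gene that was lower (1.35-fold). Also higher were Bhlhe40, Il1r2 (a decoy receptor for interleukin 1) at 2.05-fold, Hcar2 at 2.05-fold, Wfdc17 at 2.01-fold, Flrt2, Cish, Fabp4, Fbxo36, Mtss1, Glipr2, Ptges, Coq9 and Cxadr, at 1.44-fold (Cxadr) to 2.05-fold, with adjusted p of at most 0.0494. Il1r2 (mean log2 level 4.86 over all arrays) and Cxadr (4.92) lay below the array medians, as Zfp229 does, so what their folds can show is unknown. Calls of this block lie outside the rule for naming, and the genes were named from them after their values were seen. Bhlhe40 and Pgd are also named elsewhere as members of their lists. The planned fixed run factor called 2 genes, Plod2 (adjusted p = 0.0141) and 1 olfactory receptor gene. Without the block their adjusted p lay between 0.5 and 0.999. The block changed only the spread, not the fold.

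**Figure D3:**
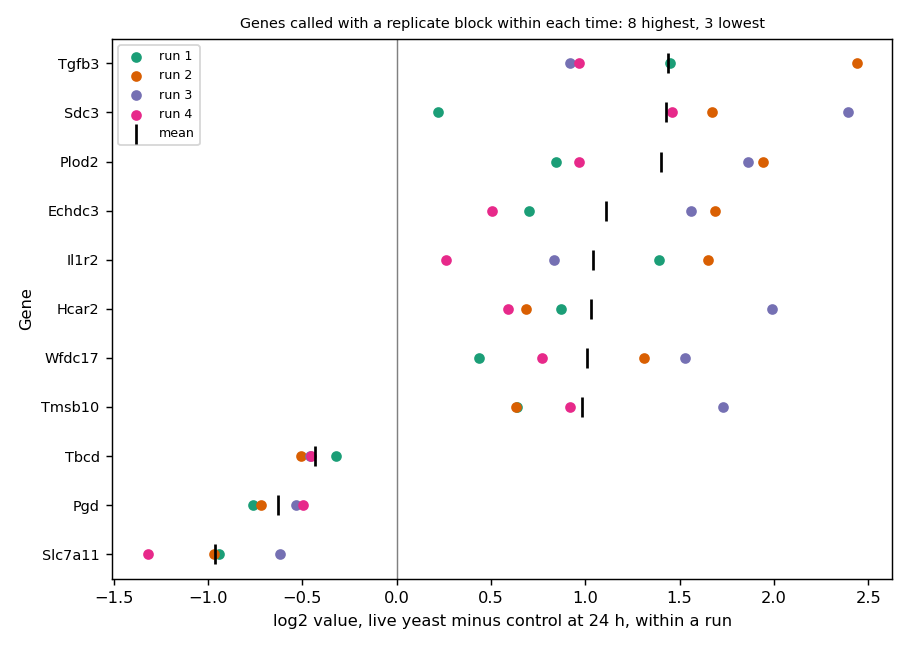
Difference in log2 level, live yeast minus control at 24 h, within each of the 4 runs (coloured points) for 11 of the 23 genes called with the run block within each time; black ticks give the mean. All 4 runs lie on the same side of 0 for each gene shown.

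Live and heat-killed yeast at 24 h were compared to find what depends on the yeast being alive. The hypoxia list rose 1.43-fold on average with live over heat-killed yeast, with 25 of 29 members higher (mean log2 8.44 ± 0.23 against 7.92 ± 0.34, SD, n = 4; 7.89 in control cells). The glycolysis list rose 1.36-fold, with 15 of 17 members higher (10.43 ± 0.19 against 9.98 ± 0.21; 10.02 in control cells). Both passed camera at the preset correlation (adjusted p = 5.89e-16 and 1.36e-13) and were the only 2 calls in any comparison that held with an estimated correlation (adjusted p = 0.0221 with an estimated correlation for both). With the run block within each time, which uses the pairing of arrays, neither held with an estimated correlation (adjusted p = 0.0575 for both). Selenbp1, a methanethiol oxidase, was 2.71-fold higher (log2 1.44 ± 0.38 SE, n = 4 per group), Bhlhe40 2.04-fold (1.03 ± 0.25), Egln1 1.85-fold (0.89 ± 0.21) and Eno2 2.2-fold (1.14 ± 0.36). The mitophagy receptor Bnip3 was 3.09-fold higher (1.63 ± 0.48) and Ankrd37 3.08-fold (1.62 ± 0.54), both chosen after their values were seen. Adjusted over the list alone, 10 hypoxia genes passed (Egln1 and Bhlhe40 at 0.00616, Selenbp1 at 0.00819) and 3 glycolysis genes (Eno2, Hk2 and Pgam1, all at 0.0405).

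Both lists were higher with live than with heat-killed yeast in 4 of 4 runs, by 0.10, 0.57, 1.03 and 0.38 log2 for hypoxia and by 0.13, 0.61, 0.77 and 0.28 for glycolysis. No single array or run left out changed these 2 calls at the preset correlation or moved either mean by more than 1.5-fold. Exact permutation of the array means gave p = 0.0571 for each (p = 0.742 after adjustment over 39 lists), and the self-contained test fry gave an adjusted p = 0.0851 for each. With limma, 0 genes passed over all 19938, with 579 at an unadjusted p under 0.05. The 5 smallest p-values, which did not pass, included Grhpr, glyoxylate reductase, 1.63-fold higher (0.70 ± 0.14 SE), Bsg, the lactate-transporter chaperone basigin, 1.45-fold higher (0.53 ± 0.11), and Selenbp2, 2.39-fold higher (1.26 ± 0.28). Ribosome biogenesis was lower with live yeast (mean log2 −0.19, 42 of 45 members, 4 of 4 runs at −0.16, −0.25, −0.16 and −0.20), with Nop56, a core protein of ribosomal RNA processing particles, 1.3-fold lower. It passed camera at the preset correlation (adjusted p = 5.75e-12) and not otherwise (adjusted p = 0.423 with an estimated correlation), and no array left out changed that. DNA replication (−0.23, 47 of 49 members lower, adjusted p = 1.21e-06) and the chaperone list (0.12, 24 of 32 higher, adjusted p = 0.011) were called at the preset correlation only (adjusted p = 0.837 with an estimated correlation for both). DNA replication was not called without live 24 h replicate 3 (−0.08), heat-killed 24 h replicate 4 (−0.11) or run 3 (−0.06), and was −0.12 without live 24 h replicate 1 and −0.49 without live 24 h replicate 4. The chaperone mean was −0.01 without live 24 h replicate 3, was not called without heat-killed 24 h replicate 2 (0.11) or 4 (0.08) or run 3 (0.03), and was 0.21 without live 24 h replicate 4.

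Live yeast was compared with control cells at 2 h to find early changes. Immediate early genes, which are transcribed within minutes of a signal, were higher in 28 of 33 members, with a mean log2 level of 7.80 ± 0.38 (SD, n = 4) against 7.53 ± 0.14. The transcription factor Egr2 was 2.08-fold higher (log2 1.06 ± 0.34 SE, n = 4 per group; 0.49 without live 2 h replicate 2), Klf2 1.86-fold (0.90 ± 0.29; 0.42 without run 2) and Junb 1.65-fold (0.73 ± 0.24). The monocyte-attracting chemokines Ccl7 and Ccl2 were 1.91-fold (0.93 ± 0.35) and 1.69-fold higher (0.76 ± 0.38). Of the hypoxia list, 21 of 29 members were higher (7.87 ± 0.16 against 7.66 ± 0.14), with Bhlhe40 at 1.67-fold (0.74 ± 0.25). Camera at the preset correlation called 6 lists, all higher: immediate early genes (mean log2 0.28, adjusted p = 1.33e-07), hypoxia (0.21, adjusted p = 2.87e-05), phagocytic and pattern recognition receptors (0.08, 30 of 38, adjusted p = 0.0114), NF-kB (0.10, 23 of 39, adjusted p = 0.0236), actin (0.07, 19 of 37, adjusted p = 0.0236) and inflammasome genes (0.10, 8 of 15, adjusted p = 0.0392). None held with an estimated correlation (adjusted p = 0.394 for immediate early, hypoxia, receptor and inflammasome genes and 0.822 for NF-kB and actin genes with an estimated correlation), and 0 members of any of the 6 passed adjusted over the list alone without a run block.

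The immediate early mean at 2 h, live against control, was higher in 4 of 4 runs (0.19, 0.71, 0.06 and 0.14), and without live 2 h replicate 2 it was 0.09 and without run 2 0.13. Hypoxia was higher in 3 of 4 runs (−0.005, 0.53, 0.23 and 0.11) and was 0.11 without run 2. The receptor list was higher in 4 of 4 runs and was not called without live 2 h replicate 1 (0.08) or 2 (0.04), control 2 h replicate 3 (0.07) or run 2 (0.02). The NF-kB list was not called without live 2 h replicate 2 (0.02) or control 2 h replicate 3 (0.07) or 4 (0.07), and was 0.19 without control 2 h replicate 2. The actin list lost its call without live 2 h replicate 1 or 4 or control 2 h replicate 2 or 3 (0.03 to 0.05), and the inflammasome list without 6 of the arrays (0.05 to 0.11). Exact permutation gave p = 0.257 for immediate early genes, 0.114 for hypoxia and 0.2 for receptors. With limma, 0 of 19938 genes passed, with 618 at an unadjusted p under 0.05 (smallest adjusted p = 1). With the run block within each time 1223 genes lay under 0.05 unadjusted, and again 0 passed. Values that did not pass included Satb1, a chromatin organiser at a log2 level of 3.95 against 4.47, below the array medians, 1.43-fold lower, and the receptor P2ry10b, 2.27-fold higher (1.18 ± 0.31 SE).

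Heat-killed yeast was compared with control cells at 24 h to find what dead yeast, added with antibody, changes. All 19 members of the cholesterol biosynthesis list, targets of SREBP2, were lower, with a mean log2 level of 8.23 ± 0.10 (SD, n = 4) against 8.52 ± 0.20 in control cells. The list was lower with live yeast against the same control arrays too (mean log2 −0.21). Between live and heat-killed yeast at 24 h it was not called (mean log2 0.07, camera adjusted p = 0.307). Insig1, which holds SREBP2 in the endoplasmic reticulum, was 1.56-fold lower (log2 −0.65 ± 0.31 SE, n = 4 per group; −0.39 without run 2) and isopentenyl isomerase Idi1 1.53-fold (−0.61 ± 0.31). Endoplasmic reticulum chaperones were lower in 25 of 32 members (9.45 ± 0.10 against 9.65 ± 0.26), with the disulfide isomerase Pdia6 1.54-fold lower (−0.63 ± 0.24) and calreticulin (Calr) 1.4-fold (−0.48 ± 0.18). The NRF2 list was lower in 21 of 28 members, with Pgd 1.4-fold lower (−0.49 ± 0.20). Camera at the preset correlation called cholesterol (mean log2 −0.28) and chaperones (−0.20) at adjusted p = 5.96e-10 each and NRF2 (−0.16) at adjusted p = 6.67e-06, and none held with an estimated correlation (adjusted p = 0.312 for all 3 with an estimated correlation). Adjusted over the list alone, 0 members passed without a run block, and 5, 13 and 3 with the run block within each time. Cholesterol was lower in 3 of 4 runs (−0.45, −0.57, 0.01 and −0.13; exact permutation p = 0.0571), and no single array or run left out changed its call or moved its mean by more than 1.5-fold. Chaperones were lower in 4 of 4 runs (−0.21, −0.13, −0.43 and −0.04; exact permutation p = 0.229), with a mean of −0.09 without control 24 h replicate 3 and −0.13 without run 3. NRF2 was lower in 3 of 4 runs (−0.26, −0.38, 0.01 and −0.02; exact permutation p = 0.229), with a mean of −0.10 without control 24 h replicate 2 and −0.09 without run 2.

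Another 6 lists were called at the preset correlation in heat-killed yeast against control at 24 h, all lower. They were DNA replication (mean log2 −0.16, adjusted p = 7.2e-06), proteasome (−0.06, adjusted p = 0.00876), and lipid metabolism (−0.05), inflammasome (−0.07), mitosis (−0.05) and heat shock genes (−0.04), each of these last 4 at adjusted p = 0.0481. None held with an estimated correlation (adjusted p from 0.312 to 0.852 with an estimated correlation). DNA replication was not called without control 24 h replicate 4 (−0.04) or run 2 (−0.05), and was −0.05 without heat-killed 24 h replicate 1, −0.09 without control 24 h replicate 2 and −0.27 without control 24 h replicate 3 or heat-killed 24 h replicate 4. The mitosis mean was above 0 without control 24 h replicate 2 (0.03), control 24 h replicate 4 (0.04) or heat-killed 24 h replicate 3 (0.02), and the lipid mean without control 24 h replicate 2 (0.05). The proteasome mean lay between −0.12 and −0.03 over the arrays left out, the inflammasome mean between −0.13 and −0.03 and the heat shock mean between −0.07 and −0.03, each with its call lost without several arrays. With limma, 0 of 19938 genes passed, with 413 at an unadjusted p under 0.05 (smallest adjusted p = 1). Acsbg1, an acyl-CoA synthetase, had the largest fold of the 5 smallest p-values (1.47-fold higher, not passed).

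With heat-killed yeast at 2 h, Zfp229, a zinc finger gene measured by probe set 10442250, rose 1.67-fold over control cells. Its log2 level was 4.93 ± 0.08 (SD, n = 4) against 4.19 ± 0.12, below the array medians, and it was higher in 4 of 4 runs (0.76, 0.62, 0.97 and 0.60). It was the only gene of 19938 that limma called here (adjusted p = 0.0491), with 818 at an unadjusted p under 0.05, and the call was lost without any 1 of 18 of the 24 arrays, each array of heat-killed or control cells at 2 h among them, and with median scaling, quantile normalization or cyclic loess (adjusted p = 0.106, 0.173 and 0.209). The fits that use the pairing of arrays lost it too (adjusted p = 0.098 with the fixed run block and 0.14 with the run block within each time). The other call of Zfp229, in control cells at 24 h against 2 h, rests on the same 4 control arrays at 2 h, so the 2 calls are not independent. Between heat-killed yeast and control at 2 h, no list was called without a run block (smallest camera adjusted p = 0.0738, immediate early genes, mean log2 0.15, 22 of 33 members higher; adjusted p = 0.997 with an estimated correlation). With the fixed run block camera called immediate early genes (adjusted p = 0.0447), and with the run block within each time it called 4 lists at the preset correlation: immediate early genes and, lower, histone genes (−0.35, 8 passing adjusted over the list alone), both at adjusted p = 0.00413, the integrated stress response (lower, −0.14) and, higher, receptors (0.07), both at adjusted p = 0.0174. None of the 4 held with an estimated correlation in that fit (adjusted p = 0.921 to 0.993 with an estimated correlation). Among values that did not pass, Sh3pxd2a, a podosome scaffold, was 1.65-fold higher. With live yeast at 2 h the probe set used for it was higher than in control cells as well (log2 0.63). Another probe set of the gene was not (log2 −0.05).

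Between live and heat-killed yeast at 2 h, glycolysis genes were higher with live yeast in 15 of 17 members (mean log2 level 9.98 ± 0.07 against 9.80 ± 0.29, SD, n = 4), with Slc2a1 1.36-fold higher (log2 0.44 ± 0.27 SE; 0.05 without run 3 and 0.78 without run 4). Hypoxia genes were higher in 24 of 29 members (7.87 ± 0.16 against 7.73 ± 0.14), and nuclear genes of the respiratory chain were lower in 50 of 59 (mean log2 −0.05), with Ndufb6, a complex I subunit, 1.13-fold lower (log2 −0.18; −0.12 without run 3). Camera at the preset correlation called glycolysis (0.19, adjusted p = 0.00234), hypoxia (0.14, adjusted p = 0.0164), respiratory chain (adjusted p = 0.0223), immediate early (0.13, adjusted p = 0.0223), lysosome (0.06, adjusted p = 0.0318) and actin genes (0.07, adjusted p = 0.0391), and none of the 6 held with an estimated correlation (adjusted p = 0.975 for all 6 with an estimated correlation). Glycolysis and hypoxia were higher in 3 of 4 runs (0.08, 0.35, 0.46 and −0.15; 0.24, 0.31, 0.22 and −0.22), and the exact permutation p was 0.371 and 0.2. Glycolysis was not called without heat-killed 2 h replicate 2 (0.12) or 3 (0.09), run 2 (0.13) or run 3 (0.09), and was 0.28 without heat-killed 2 h replicate 4. Hypoxia was not called without heat-killed 2 h replicate 1 (0.10) or 3 (0.10), live 2 h replicate 2 (0.07), or runs 1 (0.11), 2 (0.08) or 3 (0.11), and was 0.26 without run 4. The respiratory chain was not called without live 2 h replicate 2 (−0.02) or 4 (−0.04), heat-killed 2 h replicate 1 (−0.04), 3 (−0.02) or 4 (−0.05), run 3 (−0.04) or run 4 (−0.04). The immediate early mean was −0.06 without live 2 h replicate 2, the actin mean 0.01 without heat-killed 2 h replicate 2 and the lysosome mean 0.01 without live 2 h replicate 3. With limma, 0 of 19938 genes passed, with 295 at an unadjusted p under 0.05 (smallest adjusted p = 1).

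Control cells at 24 h were compared with control cells at 2 h to find what changes without yeast. Zfp229 was 1.73-fold higher at 24 h than at 2 h (log2 level 4.98 ± 0.14 against 4.19 ± 0.12, SD, n = 4; limma adjusted p = 0.0181; 4 of 4 runs). It was the only gene of 19938 called, with 716 at an unadjusted p under 0.05, where 997 would be by chance. The count was 0 without control 2 h replicate 1, 3 or 4 or control 24 h replicate 2, 3 or 4, and 2 without heat-killed 2 h replicate 3. With median scaling, quantile normalization or cyclic loess the Zfp229 call was lost too (adjusted p = 0.0719, 0.0801 and 0.0834). Its call with heat-killed yeast at 2 h was made against the same 4 control 2 h arrays. A low level in those arrays alone would give both calls. Inflammasome genes were higher at 24 h in 14 of 15 members (mean log2 0.24), with Il1b, the precursor of interleukin 1β, 2.08-fold higher (1.06 ± 0.36 SE; 0.70 without control 2 h replicate 3). They passed camera at the preset correlation (adjusted p = 0.000261), and no array left out changed that. They did not pass with an estimated correlation (adjusted p = 0.0678) or with fry (adjusted p = 0.515). By exact permutation they passed unadjusted (p = 0.0286, the smallest possible) and not after adjustment over 39 lists (p = 0.744). The integrated stress response list, targets of ATF4, was higher in 35 of 38 members (8.98 ± 0.15 against 8.61 ± 0.46), with the transcription factor Ddit3 2.78-fold higher (1.47 ± 0.56) and the glutathione-degrading enzyme Chac1 2.05-fold (1.04 ± 0.43; 0.68 without run 4). Its mean log2 of 0.37 (adjusted p = 1.11e-10; adjusted p = 0.404 with an estimated correlation) was 0.18 without control 2 h replicate 4. Of the other 10 lists called at the preset correlation, none held with an estimated correlation (adjusted p from 0.248 to 0.929 with an estimated correlation). Higher were hypoxia (0.24; 0.15 without control 24 h replicate 1), chaperones (0.17; 0.06 and not called without control 24 h replicate 3; 0.27 without control 24 h replicate 4), NF-kB (0.25; 0.11 and not called without control 24 h replicate 3), autophagy (0.13; 0.08 without control 2 h replicate 1 or 4), apoptosis regulators (0.08; 0.06 and not called without control 24 h replicate 2), glycolysis (0.12), cytosolic ribosomal proteins (0.04; 0.02 without control 2 h replicate 4) and p53 targets (0.07). Lower were ribosome biogenesis (−0.14; −0.07 and not called without control 24 h replicate 2) and mitosis (−0.14), and glycolysis, p53 targets and mitosis each lost their call without at least 4 single arrays.

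Whether the effect of yeast differed between 2 h and 24 h was tested by interaction terms. The difference between live and heat-killed yeast was larger at 24 h than at 2 h for the hypoxia list (mean log2 0.38, 19 of 29 members; camera adjusted p = 3.02e-05) and more negative for ribosome biogenesis (−0.19, 39 of 45; camera adjusted p = 1.31e-07). Neither held with an estimated correlation (adjusted p = 0.96 for both with an estimated correlation). No single array left out changed those 2 calls, and the hypoxia value was 0.24 without run 3. The effect of live yeast against control was more negative at 24 h for DNA replication (−0.37, 47 of 49; camera adjusted p = 1.56e-11; adjusted p = 0.753 with an estimated correlation), with −0.22 without live 24 h replicate 3 and −0.63 without live 24 h replicate 4. The effect of heat-killed yeast was more negative at 24 h for cholesterol biosynthesis (−0.31, 18 of 19; camera adjusted p = 9.95e-06; adjusted p = 0.673 with an estimated correlation), a call no array left out changed. Camera called 13, 11 and 5 lists for the live, heat-killed and live-minus-heat-killed interactions, and 0 held with an estimated correlation. With limma, 0 genes passed for any of the 3, with 796, 664 and 335 at an unadjusted p under 0.05. For Chordc1 the live interaction, live minus control at 24 h less live minus control at 2 h, was −0.78 ± 0.16 SE and did not pass over all genes.

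The live and heat-killed effects share their control arrays, which alone makes them correlate across genes. At 2 h their log2 fold changes correlated at r = 0.697 across 19938 genes, where unchanged groups set against the same controls gave 0.5 over 100 simulated draws. At 24 h the correlation was 0.514, against 0.499 simulated. The simulation takes the arrays as independent and ignores the runs, which can themselves raise the correlation, so the excess over 0.5 at 2 h is no measure of a shared response. Within single runs the correlations were 0.541 to 0.658 at 2 h and 0.341 to 0.559 at 24 h. With the controls split between the arms the correlations were 0.086, 0.146 and −0.088 at 2 h and −0.036, −0.165 and 0.020 at 24 h, and with each arm taken from different runs they were 0.132, 0.171 and 0.150 at 2 h and −0.013, 0.145 and 0.067 at 24 h. Splitting the controls by run leaves run offsets of opposite sign in the 2 effects, which lowers their correlation. The split values therefore do not show that no shared response remains. With each arm taken from different runs, the 2 effects share no array and no run. Those values were all above 0 at 2 h (0.132 to 0.171) and lay on both sides of 0 at 24 h. They come from the same arrays regrouped, so their range is no measure of error. Genes are not independent replicates, so no p is given. Without a run block, live yeast against control had 0 called genes at either time. The 2 arms could therefore share no called gene, and that count says nothing about a shared response.

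Several lists written before the data were examined were not called between live yeast and control cells at 24 h without a run block. Interferon-stimulated genes had a mean log2 difference of 0.02 (camera adjusted p = 0.741, 17 of 32 members higher), and respiratory chain genes −0.02 (adjusted p = 0.243). Mitochondrial dynamics and mitophagy genes were at 0.10 (adjusted p = 0.654), p53 targets at 0.11 (adjusted p = 0.205), antigen presentation at 0.13 (adjusted p = 0.205) and integrated stress response genes at −0.05 (adjusted p = 0.0851). With the run block within each time camera at the preset correlation called the integrated stress response (adjusted p = 0.0139; 0.657 with an estimated correlation) and antigen presentation (adjusted p = 0.0333; 0.272 with an estimated correlation), and with the fixed run block the integrated stress response (adjusted p = 0.0283). Apoptosis regulators (0.04), autophagy (0.02), lysosome and phagosome (−0.01), receptors (−0.03), inflammasome (−0.01), metallothionein and metal handling (0.02), lipid metabolism (0.004), actin (0.07), cytosolic ribosomal proteins (−0.02), cyclins D and CDK inhibitors (0.04) and histone genes (−0.03) had adjusted p between 0.279 and 0.789. Macrophage identity genes were at −0.03 (adjusted p = 0.562). The markers of other cell types were at 0.11 for T cells, 0.001 for B cells, 0.10 for neutrophils, 0.02 for fibroblasts and 0.05 for epithelium, with adjusted p from 0.224 to 0.896. The highest marker of each, averaged over the 24 arrays, was Cd5 at 7.33, Bank1 at 8.14, S100a8 at 9.08, Col1a1 at 6.13 and Krt8 at 6.28, against 12.98 for the macrophage lysozyme Lyz2 and 12.31 for Tyrobp. In none of the 10 comparisons did the mean and the median of a called list differ in sign.

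**Figure D4:**
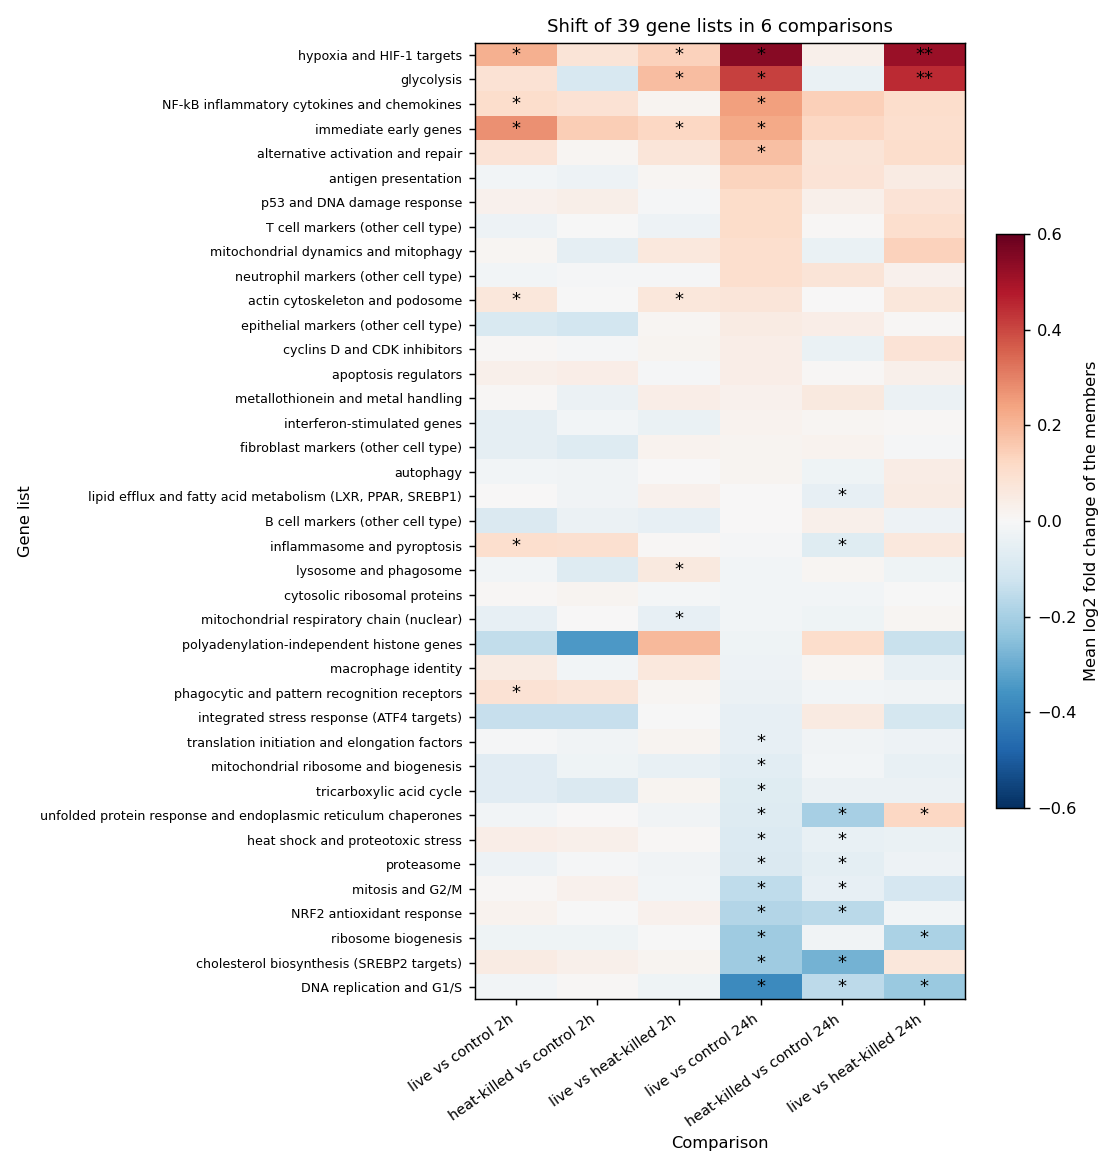
Mean log2 difference of the 39 gene lists (vertical) in 6 comparisons (horizontal), coloured from −0.6 (blue) to 0.6 (red); 1 asterisk marks a call by camera at its preset correlation and 2 asterisks a call that also held with an estimated correlation. Hypoxia and glycolysis, live against heat-killed yeast at 24 h, carry the only 2 double asterisks, and neither held with the run block within each time (adjusted p = 0.0575 for both).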

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

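Of the tests in this part, leaving out arrays or runs for the live-yeast pattern and the test for yeast RNA were chosen only after the result was seen, as was the run block within each time. The rules for reading the tests of a single array or run, of yeast RNA and of a further step in culture were made stricter after their values were seen, and that of yeast RNA was changed more than once.

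In 4 of 104 groups of 4 arrays, 1 array stood far from the other 3, where about 5.2 would by chance at 1 in 20. Tex43 was at 5.93 log2 in control 2 h replicate 4 (others 5.52 to 5.55). Haao was at 5.17 in control 24 h replicate 3 (others 5.40). Zim1 was at 4.18 in heat-killed 24 h replicate 2 (others 4.57 to 4.64). Bach2os was at 6.08 in live 24 h replicate 1 (others 5.83 to 5.86). None of these 4 genes passed over all genes in the fits without a block.

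By interaction tests with camera at the preset correlation, the effect of yeast differed between 2 h and 24 h for 13 lists with live yeast, 11 with heat-killed yeast and 5 for live minus heat-killed yeast, and for 0 with an estimated correlation. Given here are the 10 results whose list was among the 3 called lists with the smallest camera p in the same comparison at 2 h or at 24 h. For live yeast against control these were the hypoxia list (mean log2 0.33, adjusted p = 0.794 with an estimated correlation), phagocytic and pattern recognition receptors (−0.12, adjusted p = 0.698), ribosome biogenesis (−0.19, adjusted p = 0.632) and DNA replication (−0.37, adjusted p = 0.753). For heat-killed yeast they were endoplasmic reticulum chaperones (−0.20, adjusted p = 0.566), NRF2 targets (−0.16, adjusted p = 0.673) and cholesterol biosynthesis (−0.31, adjusted p = 0.673). For live minus heat-killed yeast they were hypoxia (0.38), glycolysis (0.26) and ribosome biogenesis (−0.19), each at adjusted p = 0.96 with an estimated correlation. The live hypoxia call was lost without control 2 h replicate 1 (0.27), live 24 h replicate 2 (0.27), control 24 h replicate 3 (0.28) or 4 (0.31), or live 2 h replicate 4 (0.28). The receptor call was lost without control 24 h replicate 1 (−0.10) or 2 (−0.05), live 2 h replicate 2 (−0.08), control 2 h replicate 3 (−0.11), or live 24 h replicate 3 (−0.08) or 4 (−0.11), and its value was −0.18 without live 24 h replicate 2. The live ribosome biogenesis value was −0.13 without live 24 h replicate 2, and the call was lost without run 3 (−0.08). The heat-killed chaperone value was −0.09 without control 24 h replicate 3. The NRF2 value was −0.10 without control 24 h replicate 2, −0.26 without control 2 h replicate 3 and −0.08 without heat-killed 2 h replicate 3, and the call was lost without run 1 (−0.12). The glycolysis call was lost without heat-killed 2 h replicate 1 (0.20) or 4 (0.17), live 24 h replicate 2 (0.21) or heat-killed 24 h replicate 3 (0.19).

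For the higher hypoxia and glycolysis transcripts with live yeast at 24 h, the tables argue against 1 technical explanation. Among 10000 random lists matched on mean level, the hypoxia shift of 0.52 lay at percentile 100 (range of the random lists −0.11 to 0.16), which argues against a normalization tied to brightness. RNA of the live yeast binding mouse probes cannot be told apart: the upper bounds of the ribosomal protein (0.0452) and translation factor lists (0.0516) lay below the lifts of 0.0982 and 0.268 that the signal added to the glycolysis list would give them, but that takes the same added signal on every probe, and no table measures how much yeast RNA each probe binds. A single run stays open, since without run 3 the hypoxia shift was 0.35 against a bound of 0.26, a margin smaller than its SE of 0.17, and a further step of the change seen in control cells over time cannot be told apart, because the integrated stress response shift of −0.11 (bound 0.40) is set against a control change of 0.37 with an SE of 0.23, too uncertain to predict from. A host response to living yeast, such as lower oxygen in the culture or HIF-1 activity set by the infection, may be a candidate explanation and was not tested.

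For the lower DNA replication and ribosome biogenesis transcripts with live yeast at 24 h, the ribosome biogenesis shift of −0.21 lay at percentile 0 of 10000 random lists matched on mean level (−0.14 to 0.09), which argues against a normalization tied to brightness. A single array as the source of the DNA replication shift cannot be told apart, since without live 24 h replicate 3 it was −0.24, farther from 0 than a bound of −0.19 by less than its SE of 0.28. Slower growth of infected cells may be a candidate explanation and was not tested.

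For the lower chaperone and cholesterol transcripts with heat-killed yeast at 24 h, the chaperone shift of −0.20 lay at percentile 0 of 10000 matched random lists (−0.11 to 0.06), which argues against a normalization tied to brightness. A single array as the source of the chaperone shift cannot be told apart, since without control 24 h replicate 3 it was −0.09, nearer to 0 than a bound of −0.10 by less than its SE of 0.13. The lower cholesterol list was not particular to heat-killed yeast. With live yeast against the same control arrays it was lower too (mean log2 −0.21, 18 of 19 members, camera adjusted p = 4.86e-05 at the preset correlation). Live and heat-killed yeast differed by 0.07 (camera adjusted p = 0.307). Lipid taken up with the yeast lowering the demand for sterol synthesis may be a candidate explanation and was not tested.

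The 8 arrays of each comparison were split into 4 and 4 in 35 ways, the real one included. At least as many genes as in the real split were called in 35 of 35 splits for live against control at 2 h (real 0, highest other 24), live against control at 24 h (0, 45), heat-killed against control at 24 h (0, 1), live against heat-killed at 2 h (0, 932) and live against heat-killed at 24 h (0, 8). For heat-killed against control at 2 h it was 3 of 35 (real 1, highest other 1), so chance was not excluded. For control at 24 h against 2 h it was 1 of 35 (real 1, highest other 0). That is the smallest share 35 splits can give, and several comparisons were tested this way. The call of that 1 gene was lost with only the control arrays fitted and under 3 normalizations, so chance was not excluded for it either. At an unadjusted p under 0.05 the real split of the control arrays gave 716 genes, and 17 of the 35 splits, the real one included, gave at least as many (highest 2141). For the interactions 100 of 100 relabellings gave as many (real 0 each, highest other 16 for live, 3 for heat-killed and 680 for live minus heat-killed). For called lists the counts were 27 of 35 (live against control at 2 h, real 6, highest other 15), 9 of 35 (live against control at 24 h, 16, 21), 35 of 35 (heat-killed against control at 2 h, 0, 12), 19 of 35 (heat-killed against control at 24 h, 9, 16), 22 of 35 (live against heat-killed at 2 h, 6, 14) and 33 of 35 (live against heat-killed at 24 h, 5, 17), so chance was not excluded for the 5 counts of lists above 0. Where the real count is 0, of genes or of lists, every split gives as many, so the comparison says nothing.

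The splits with 24, 45 and 932 genes set whole runs against each other and part 0 of the 4 pairs, so they point to the structure of the runs. Among the 7 other splits that part all 4 pairs as the real one does, the highest number of genes was 0 in each comparison, and the highest number of lists was 7, 15, 6, 11, 3 and 14 in the order given for lists, against the real 6, 16, 0, 9, 6 and 5. The 23 genes of the run block within each time, live against control at 24 h, were set against 8 splits within runs, of which 1, the real one, gave as many (highest other 1), and 8 splits are too few for a share under 0.05.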

How the results depend on the processing

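Chosen only after the result was seen were the run block within each time, the runs left out, the exact permutation test of list means and the overlap from different runs. In what follows the cause was not tested unless fewer arrays or genes are the change itself.

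Signal over background is not given in the deposited table, so it is unknown what low levels such as that of Zfp229 can show, and 4 arrays per group with a median SE of 0.14 log2 limit what single genes can show. Of 83 called lists, 82 kept direction and call with the run as a fixed block (p53 targets in control cells lost theirs), 82 with only the arrays of the contrast, 81 with trended robust moderation, 75 with array weights, 57 without the dimmer genes, 82 with the mean of probe sets, 72 with median scaling, 48 with quantile normalization and 50 with cyclic loess. With the run block within each time 70 of 71 did (the inflammasome list, heat-killed against control at 24 h, lost its call), with an estimated correlation 2, with fry 0, and with the exact permutation test 3 of 54. With run 1, 2, 3 or 4 left out, 59, 58, 45 and 72 of the 83 did. The random block ran no list tests, and the block within each time cannot give control 24 h against 2 h.

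The replicate block changed these counts of called genes and no other. For live against control at 24 h, the fixed block gave 2 and the block within each time 23, where 0 were called without a block. For heat-killed against control at 2 h both gave 0, Zfp229 having an adjusted p of 0.098 with the fixed block. For the live-minus-heat-killed interaction the fixed, random and within-time blocks each gave 1, an olfactory receptor gene. Of 381 gene values, 379 kept direction and call with the fixed block, the exceptions being Zfp229 at 2 h and Plod2. Of 330 with the block within each time, 316 did. That block also raised the number of genes at an unadjusted p under 0.05, where 997 would be by chance. It was 1737 for heat-killed against control at 2 h and 982 at 24 h. For live against heat-killed yeast it was 546 at 2 h and 1342 at 24 h. For the live, heat-killed and live-minus-heat-killed interactions it was 1749, 1271 and 764. Beside the calls without a block, camera at the preset correlation called 11 more lists of 307 with the fixed block and 23 more of 280 with the block within each time, of which 4 in heat-killed against control at 2 h, 3 in live against control at 2 h, 2 in live against control at 24 h, 1 in heat-killed against control at 24 h, 2 and 3 in live against heat-killed at 2 h and 24 h, and 0, 3 and 5 in the live, heat-killed and live-minus-heat-killed interactions. With an estimated correlation the block within each time called 0 lists in each comparison, hypoxia and glycolysis, live against heat-killed at 24 h, included (adjusted p = 0.0575 for both). More lists were also called with only the arrays of the contrast (11), array weights (15), the dimmer genes left out (20 of 267), the mean of probe sets (1), median scaling (7), quantile normalization (2) and cyclic loess (8), with run 1, 2, 3 or 4 left out (11, 24, 14 and 18), and with single arrays left out (0 to 17).

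The block within each time also changed how many genes passed adjusted over the list alone. Given here are the lists where this count was 3 or more. In live against control at 24 h it was 19 for hypoxia (15 without a block), 26 for DNA replication, 9 for glycolysis, 7 for chaperones, 7 for NRF2, 4 for the integrated stress response, and 3 each for ribosome biogenesis, p53 targets and actin (each 0 without a block). In live against heat-killed at 24 h it was 17 for hypoxia (10 without a block), 11 for glycolysis (3 without a block), 4 for receptors and 3 for mitochondrial dynamics. In heat-killed against control at 24 h it was 13 for chaperones, 5 for cholesterol and 3 for NRF2. At 2 h it was 4 for immediate early genes and 3 for actin in live against control, and 8 for histone genes in heat-killed against control. In the interactions it was 5 for NRF2 and 4 for cholesterol with live yeast, and 11 for chaperones and 3 for cholesterol with heat-killed yeast.

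The call of Zfp229, heat-killed against control at 2 h, was lost (0 genes) with only the arrays of the contrast, without the dimmer genes, over all probe sets, and with median scaling, quantile normalization and cyclic loess. For control at 24 h against 2 h, 0 genes were called with only the arrays of the contrast, without the dimmer genes, and with median scaling, quantile normalization and cyclic loess, and 2 with array weights. Zfp229 is itself among the dimmer genes. Over the settings with all replicates that kept the gene, the adjusted p of Zfp229, heat-killed vs control 2h, lay between 0.0261 and 0.539, and that of Zfp229, control 24h vs control 2h, between 0.00469 and 0.176. With each of runs 1, 2, 3 and 4 left out, both counts were 0 (adjusted p of Zfp229 up to 1).

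With array weights the mitosis mean, heat-killed against control at 24 h, was 0.0082, on the other side of 0. The receptor list, live against control at 2 h, was no longer called with quantile normalization (0.098, adjusted p = 0.0503) or cyclic loess (0.101, adjusted p = 0.0545).

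With an estimated correlation the means stay as they are and these calls were lost. For live against control at 2 h they were immediate early genes (0.275), hypoxia (0.214) and receptors (0.0848), each at adjusted p = 0.394. For live against control at 24 h they were ribosome biogenesis (−0.213, adjusted p = 0.222), hypoxia (0.548, adjusted p = 0.05) and DNA replication (−0.382, adjusted p = 0.41). For heat-killed against control at 24 h they were chaperones (−0.201), NRF2 (−0.162) and cholesterol (−0.284), each at adjusted p = 0.312. For live against heat-killed at 2 h they were respiratory chain (−0.0504), hypoxia (0.139) and glycolysis (0.185), each at adjusted p = 0.975, and at 24 h ribosome biogenesis (−0.192, adjusted p = 0.423).

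With fry the same 13 calls were lost, as were hypoxia (0.519) and glycolysis (0.449), live against heat-killed at 24 h (adjusted p = 0.0851 for both). The adjusted p was 0.99 for the 3 lists of live against control at 2 h, then 0.35, 0.0561 and 0.506, then 0.958 for the 3 of heat-killed against control, then 0.985 for the 3 of live against heat-killed at 2 h and 0.632 for ribosome biogenesis at 24 h. The exact permutation p of the 15 lists, in the order given, was 0.257, 0.114 and 0.2, then 0.143, 0.0571 and 0.257, then 0.229, 0.229 and 0.0571, then 0.4, 0.2 and 0.371, then 0.114, 0.0571 and 0.0571, so none of the 15 passed by it. That permutation ignores the pairing of arrays within runs.

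Without run 1, hypoxia in live against heat-killed at 2 h was 0.105 and lost its call, and mitosis in control cells was 0.0106, on the other side of 0. Without run 2, receptors in live against control at 2 h were at 0.0208, and hypoxia and glycolysis in live against heat-killed at 2 h at 0.0812 and 0.129, each not called. Also without run 2, mitosis (0.00782), lipid metabolism (0.0259) and Il1b (0.102) in heat-killed against control at 24 h lay on the other side of 0. Without run 3, respiratory chain (−0.0445), hypoxia (0.112) and glycolysis (0.0938) in live against heat-killed at 2 h were not called, and the interaction values of translation factors with live yeast (0.00473) and of Cks2 (0.0119) and Psmc6 (0.0368) with heat-killed yeast lay on the other side of 0. Without run 4 the respiratory chain was at −0.0363 and not called.

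The correlation of the live and heat-killed effects, 0.697 at 2 h and 0.514 at 24 h, was 0.0862, 0.146 and −0.0878 at 2 h and −0.0357, −0.165 and 0.0202 at 24 h with the controls split, and 0.132, 0.171 and 0.15 at 2 h and −0.0131, 0.145 and 0.0673 at 24 h with the arms from different runs. The values with the controls split are lowered by run offsets of opposite sign in the 2 effects.

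With each of the 24 arrays left out in turn, called genes numbered 0 to 1 for heat-killed against control at 2 h (0 without 18 of the 24), 0 to 2 for control at 24 h against 2 h (2 without heat-killed 2 h replicate 3), 0 to 1 for live against control at 24 h (1 without live 24 h replicate 4) and 0 to 1 for the live-minus-heat-killed interaction (1 without heat-killed 2 h replicate 1). The receptor mean, live against control at 2 h, ran from 0.0438 to 0.118. In live against heat-killed at 2 h the respiratory chain ran from −0.0946 to −0.0193, hypoxia from 0.0686 to 0.2, glycolysis from 0.0903 to 0.278, immediate early genes from −0.0596 to 0.245, Egr2 from −0.016 to 0.779 and Nr4a3 from −0.0986 to 0.431. In heat-killed against control at 24 h mitosis ran from −0.156 to 0.036 and lipid metabolism from −0.157 to 0.0475. The value for Il1b, heat-killed vs control 24h, ran from −0.513 to 0.01. In live against control at 24 h chaperones ran from −0.208 to 0.0337 and mitosis from −0.328 to 0.0206, and in live against heat-killed at 24 h chaperones from −0.00711 to 0.207. Among the interactions mitosis with heat-killed yeast ran from −0.18 to 0.0544 and with live yeast from −0.334 to 0.0154, proteasome with live yeast from −0.116 to 0.00323 and chaperones with live yeast from −0.189 to 0.0522.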

Other observations

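The run block within each time, by which Slc7a11 and Pgd were called, was chosen only after the result was seen.

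In the cells with live yeast at 24 h, 2 genes that feed antioxidant defence had lower levels than in control cells, and neither passed without the run block (adjusted p = 0.999 for both). Slc7a11, which imports cystine for glutathione synthesis, was at 8.17 ± 0.73 log2 with live yeast against 9.14 ± 0.45 in control cells (SD, n = 4), and Pgd, which makes NADPH in the pentose phosphate pathway, at 10.12 ± 0.20 against 10.75 ± 0.16. Pgd was 1.4-fold lower with heat-killed yeast too, which did not pass over all genes. Hmox1, the haem-degrading enzyme of the same NRF2 list, went the other way and was 1.52-fold higher with live yeast (0.61 ± 0.20 SE), which did not pass over all genes either.

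Among chaperone genes, P4hb, a protein disulfide isomerase, was 1.59-fold higher with live yeast than in control cells at 24 h (log2 0.67 ± 0.21 SE) and 1.73-fold higher than with heat-killed yeast (0.79 ± 0.21), where it was the 1 member of its list that passed adjusted over the list alone. It did not pass over all genes. The chaperone list went the other way in live against control at 24 h, with 24 of 32 members lower (mean log2 −0.08).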
